A study of Mus musculus with 8 samples.

How the data were processed

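RNA sequencing of 8 libraries of FACS-sorted mouse beta cells was used, 4 from mice with both Adar alleles floxed (KO) and 4 from mice with 1 floxed allele (Het), with groups and replicate numbers taken from the sample titles. Per the labels' protocols, islets were dissociated, YFP-positive cells were sorted, and libraries were made with Takara's SMARTer kit for pico amounts of total RNA (version 3), which uses random priming of total RNA, marks strand and carries molecular identifiers. The submitters' processing notes name FastQC 0.11.8, UMI-tools, STAR 2.7.3a, HTSeq and DESeq2 1.28.1 and the mouse build mm10, without saying what each did. The annotation, the counting mode, the strand setting and any removal of duplicates are not stated, so the recovered reads may be molecules. Genes that overlap, or that share reads with near-identical copies, cannot be separated further.

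The deposited signal values are gene counts divided by 1 size factor per library, which the file calls normalized counts. In each library 100% of the values were whole multiples of the smallest value above 0, within a tolerance of 0.001 of a step, which gave back whole reads. The size factors recovered this way equalled those that DESeq2's median-of-ratios method gives on these reads (ratio 1 in each library). No row lacked a gene name. Reads per library ranged from 5.37 to 15.9 M, and normalized totals from 5.40 to 16.8 M, a 3.11-fold range. The level of expressed genes differs between libraries under the deposited scaling, and which genes set the size factors was not tested. All replicate pairs differed by more than counting noise (smallest chi-square per degree of freedom 3.77 in Het and 29.7 in KO), so no library was counted as a repeat of another. Symbols were matched to the GENCODE M21 annotation of mm10, where 42980 were found, and coordinates are those of that annotation, counted from base 1.

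The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1) of genes with a mean of at least 10 over the 8 libraries, with eBayes using a trend and robust settings, two-sided. Genotype was the only term, and the Benjamini-Hochberg adjusted p had to be under 0.05. Adjusted p-values are of this kind throughout unless another tool is named. Fold changes are on the log2(value + 1) scale, KO relative to Het, and understate the change of low genes. Under the deposited scaling limma found no difference between genes in spread beyond the trend (total degrees of freedom 128988), so its p-values rest on 1 spread shared by genes of like level. With TMM scaling the median total was 17.3 degrees of freedom per gene, and the p-values of the most changed genes are much larger there, while those of other genes are smaller or larger. The count tests, run on recovered whole reads as alternatives, were the quasi-likelihood test of edgeR 4.0.16 with filterByExpr and TMM, and DESeq2 1.42.0.

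Before the data were examined, 17 gene lists, 13 lists of cell type markers and 3 quality lists were fixed from textbook knowledge, and 31 of them had at least 3 tested members. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Each was also tested with fry, which sets a list against no change and not against other genes. Of the 31 lists, camera called 17 (12 higher, 5 lower), 1 with an estimated correlation, and fry 0. With TMM scaling fry also called 0, and with a mean of at least 200 and TMM factors 6 of 21. For 1 list (alpha cell) the median and the test's direction differ in sign. Genes named in the text follow a rule fixed in advance. It takes Adar, then the 14 genes with the largest rise and the 10 with the largest fall among those called with a mean of at least 50, groups that do not overlap and a symbol that is not a predicted gene model. It adds the 4 members with the smallest p of each list and the marker of highest mean of each cell type. Where the text names others it says so.

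Alternatives fixed in advance were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, TMM and quantile scaling, eBayes without trend or robust settings, array weights, the replicate number as a block, edgeR, DESeq2, leaving out each library, an estimated correlation, fry and a limit of 1 on the log2 fold change. Alternatives added after seeing the data were genes with a mean of at least 200 and TMM factors from them (also with an estimated correlation, with fry, and leaving out each library), the Het libraries against KO 1 and KO 2 only or against KO 3 and KO 4 only, and libraries of both sexes only. The scripts were tested on simulated counts drawn from the gene means of the Het libraries and the size factors of the 8 libraries. The simulation held 20464 genes, with 200 genes drawn to change and those that passed the filter counted. Of genes changed by a log2 of 1 and −1, limma recovered 34.0% and 17.1%, and of those changed by 2 and −2, 64.0% and 50.0%, with 5 false calls. In that simulation edgeR recovered 36.0%, 19.4%, 66.0% and 56.8%, with 6 false calls, among 20128 genes. Changes of a log2 of 1 or −1 were therefore mostly missed at this depth and number of libraries, and smaller ones were not simulated. The simulation scaled all genes of a library by 1 size factor and so held no difference in composition between libraries. Its recovery and its number of false calls therefore need not hold for the real data, whose libraries differ in composition. Intervals of read shares are exact binomial intervals at 95% and cover counting error only.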

Results

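RNA was measured in beta cells sorted from tamoxifen-treated mice with floxed alleles of Adar, the gene of the enzyme that edits adenosine to inosine in double-stranded RNA. MipCreER is a tamoxifen-inducible Cre recombinase driven by an insulin promoter, and R26R-EYFP marks the recombined cells with a yellow fluorescent protein. Mice of 1 month received 2 tamoxifen doses of 8 mg, and YFP-positive cells were sorted from dissociated islets 7 days later. The 4 KO libraries came from mice with both Adar alleles floxed, and the 4 Het libraries from mice with 1 floxed allele. The design text names islet inflammation and diabetes after Adar loss and asks for their molecular basis. The table holds normalized counts of 44343 genes, from which whole reads per library were recovered. The Het libraries held 5.93, 7.03, 12.8 and 8.10 M reads and the KO libraries 15.9, 13.0, 5.37 and 9.07 M, in the order of their numbers. The labels do not say how many mice each library came from, so p-values measure the spread between libraries.

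The 8 libraries differed in ways that genotype did not explain. Over genes with a mean of at least 200, the median level under the deposited scaling was 0.88 and 0.96 log2 units above the average library in KO 1 and KO 2. It was −0.77 in KO 3 and −0.56 in KO 4, and from −0.46 to 0.22 in the Het libraries, a 3.33-fold range in all. Olfactory and vomeronasal receptor genes, which belong to sensory neurons, took 0.0484% of reads in KO 1 (95% exact binomial interval 0.0473% to 0.0495%) and 0.0342% in KO 2 (0.0332% to 0.0352%). Their share was 0.315% in KO 3 (0.310% to 0.320%) and 0.285% in KO 4 (0.281% to 0.288%). In the Het libraries it ran from 0.0838% in Het 3 to 0.236% in Het 4. Mitochondrial genes took 17.4% of reads in KO 3 and 6.90% to 10.4% elsewhere. Most of these reads were of mitochondrial ribosomal RNA, which took 16.1% of reads in KO 3 and 5.97% to 9.10% elsewhere. Xist was at 19.2 in Het 1 and at 2343 to 7207 elsewhere, while Ddx3y, on the Y chromosome, was at 1.10 in KO 3 and 0 in KO 4 (0 reads, which allows up to 3 reads) and at 198 to 1285 elsewhere. Het 1 thus held reads of males only, KO 3 and KO 4 of females only, and the other 5 libraries of both sexes.

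**Figure D1:**
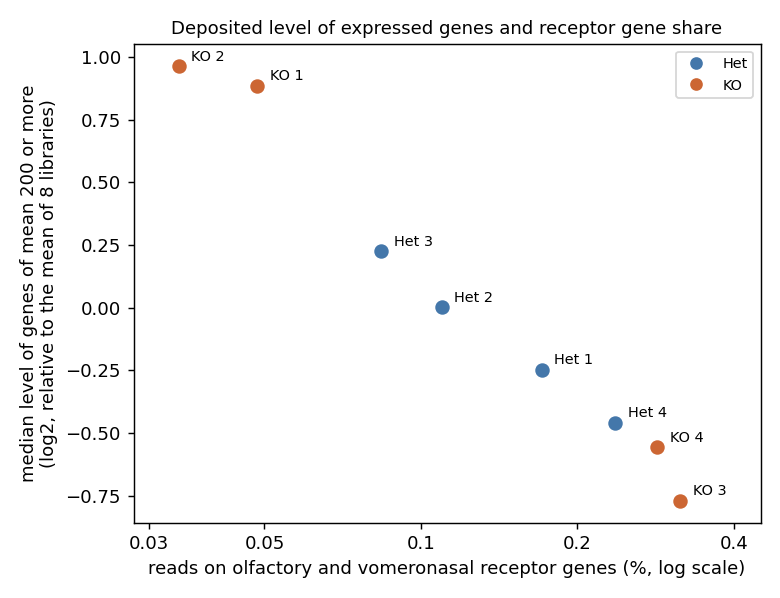
Each point is 1 library. The x axis gives the percent of reads on olfactory and vomeronasal receptor genes (log scale) and the y axis the median level, in log2 units of the deposited normalized counts, of genes with a mean of at least 200. KO 1 and KO 2 lie at the low-share end (0.0484% and 0.0342%) and KO 3 and KO 4 at the high-share end (0.315% and 0.285%), with the Het libraries between them.

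Adar itself (ENSMUSG00000027951, protein-coding, chromosome 3, 89715022 to 89753446, plus strand, mm10) was not lower in KO. Its normalized count was 943, 1173, 1187 and 744 in the Het libraries and 4030, 2365, 615 and 1343 in the KO libraries. The log2 fold change was 0.75 with a standard error of 0.58 (limma adjusted p = 0.910) and 0.53 with TMM scaling (adjusted p = 0.682). A two-sided exact permutation test of the 8 values gave p = 0.286, where the smallest p that 70 arrangements allow is 0.0286. A gene-level count takes reads from all exons, so it does not measure the floxed part, and the level of Adar does not check the labels.

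KO beta cells showed higher levels of interferons, of the chemokine Ccl5 and of interferon-induced genes. Of 21498 genes with a mean of at least 10, 198 were higher and 5 lower in KO (limma, adjusted p under 0.05), all by a log2 fold change of at least 1. At an unadjusted p under 0.05 there were 871 higher and 581 lower. Of the 203 called genes, 161 had all 4 KO values above all 4 Het values and 2 had them all below, which the choice of called genes favors. Over all 21498 tested genes, 471 and 192 were separated in this way. Chance separates 2.86% of genes, both directions together, and the total was close to that share. TMM scaling moved the median log2 fold change of all genes by −0.21 and called 137 genes higher and 8 lower, of which 114 and 1 were among those called under the deposited scaling. With whole reads, edgeR called 157 higher and 8 lower of 23320 genes and DESeq2 211 higher and 3 lower. Among 6697 genes with a mean of at least 200 and TMM factors from these genes, 404 were higher and 284 lower (58.7% higher, against 97.5% under the deposited scaling), and 118 and 23 differed by at least 1 on the log2 scale. That setting was chosen after the libraries' levels were seen. Under the deposited scaling the number of genes higher was 129 without Het 1, 105 without KO 1 and 338 without KO 3. The number lower was 1 without Het 1, 2 without Het 2, 3 without Het 3, 3 without Het 4, 18 without KO 2, 46 without KO 3 and 34 without KO 4.

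The largest rises were in the interferon system. Ccl5 (chromosome 11, 83525778 to 83530518), a chemokine that attracts T cells, went from 3.35 ± 0.95 normalized counts in Het to 961 ± 1242 in KO (SD, n = 4 each), a log2 fold change of 7.04 ± 0.40 (SE). Ifnb1 (chromosome 4, 88522025 to 88522774), interferon beta, went from 4.40 ± 2.50 to 430 ± 547, a log2 fold change of 5.74 ± 0.40. Ifna4, an interferon alpha, rose by 5.97 ± 0.40, and the interferon lambda genes Ifnl3 and Ifnl2 by 4.94 ± 0.48 and 4.69 ± 0.43. Interferon-induced genes among the 14 largest rises were Ifit2 (5.75), Ifi44 (4.93), Zbp1 (4.78), Ifit3 (4.72), Isg15 (4.62), Bst2 (4.48), Iigp1 (4.37), Gbp3 (4.28) and Ifit3b (4.24). The naming rule takes only genes whose groups do not overlap. With TMM scaling limma's adjusted p of the 14 ran from 9.56e-06 for Ifi44 to 0.00356 for Gbp3. KO 1 held the highest value of each. For Ifnb1 it was at 1250 against 148 to 167 in the other KO libraries. Ifna4, Ifnl2 and Ifnl3, as Ifit3 and Ifit3b, have near-identical relatives, and the counting of reads shared between them is not stated, so their values are uncertain within each family.

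**Figure D2:**
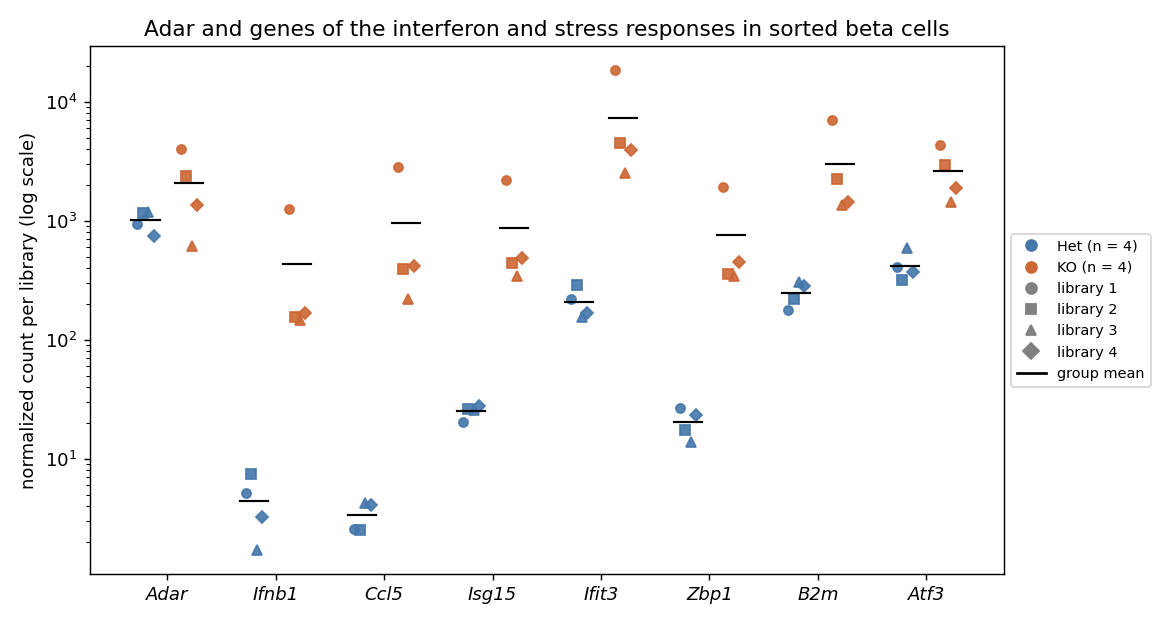
Normalized counts per library (y axis, log scale) of Adar and 7 further genes (x axis). Points are single libraries, marker shape gives the library number, color the group, and bars the group mean (n = 4). For the genes other than Adar the 4 KO values lie above the 4 Het values, and for Adar KO 3 at 615 lies below the Het range of 744 to 1187.

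Type I interferon-stimulated genes rose as a list. Of 53 tested members, 27 were called higher and 0 lower over all genes (41 and 0 at an unadjusted p under 0.05). Adjusted over the list alone, 41 were higher. The median log2 fold change was 1.91 (limma camera, adjusted p = 6.01e-90), and 1.69 with TMM scaling (adjusted p = 2.88e-72). The call did not hold with an estimated correlation (adjusted p = 0.077). Interferon-gamma-type GTPases and regulators had 14 of 25 members called higher and 0 lower (18 and 1 at an unadjusted p under 0.05; edgeR 14 and 0, DESeq2 16 and 0), and 17 higher adjusted over the list alone. Their median was 2.03 (adjusted p = 4.83e-64, and adjusted p = 0.057 with an estimated correlation). Among them Tgtp1, an interferon-induced GTPase, rose by 4.11 ± 0.43 and F830016B08Rik, of the same family, by 3.82 ± 0.40. Of the type I list, edgeR called 31 higher and 0 lower and DESeq2 37 and 0. Each of the 2 lists kept its call in 26 of 29 alternatives, most of which keep the preset correlation. Both calls were lost with fry under the deposited scaling. They were also lost with an estimated correlation, under that scaling and with a mean of at least 200 and TMM factors. Relative to the Het mean with TMM scaling, the type I list's median was 2.53 in KO 1, 1.18 in KO 2, 1.17 in KO 3 and 1.67 in KO 4.

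Genes that sense double-stranded RNA, the substrate of Adar, had 5 of 20 members called higher and 0 lower (9 and 0 at an unadjusted p under 0.05; edgeR and DESeq2 6 and 0 each) and 9 higher adjusted over the list alone. The list's median was 0.63 (limma camera, adjusted p = 2.25e-17, and adjusted p = 0.305 with an estimated correlation). Zbp1, a sensor of Z-form nucleic acid (chromosome 2, 173206612 to 173218923), went from 20.4 ± 5.92 to 765 ± 767. Ifih1, which encodes MDA5 (chromosome 2, 62595798 to 62646255), had a log2 fold change of 3.13 ± 0.54 and reached 2784 ± 3181 in KO. KO 1 held 7496 of Ifih1, against 507 to 1601 in the other KO libraries. The oligoadenylate synthetases Oas2 and Oas1a rose by 3.47 ± 0.46 and 2.76 ± 0.45. Zbp1, Ifih1, Oas2 and Oas1a are also members of the type I interferon-stimulated list. The rise of the sensing list is thus not a result separate from the rise of that list. Of 24 genes of MHC class I antigen presentation, 6 were called higher and 0 lower (16 and 0 at an unadjusted p under 0.05; edgeR 8 and 0, DESeq2 11 and 0), and 13 were higher adjusted over the list alone. Their median was 1.34 (adjusted p = 1.95e-20, and adjusted p = 0.359 with an estimated correlation). B2m, the light chain of every class I molecule, went from 248 ± 57.9 to 3010 ± 2704, a log2 fold change of 3.27 ± 0.55. KO 1 held 7023 of B2m, against 1349 to 2226 in the other KO libraries. The class I heavy chain genes H2-T24, H2-Q7 and H2-Q6 rose by 2.89 ± 0.40, 2.67 ± 0.40 and 2.62 ± 0.49, with the same uncertainty between near-identical relatives.

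Of 21 chemokines and cytokines, 6 were called higher and 0 lower (8 and 0 at an unadjusted p under 0.05; edgeR 5 and 0, DESeq2 2 and 0), and 7 were higher adjusted over the list alone. DESeq2 gave no adjusted p for Ifna4, Ifnb1, Ifnl2 and Ifnl3, which limma called higher, so its count leaves these out. The list's median was 0.53 and its mean was raised by a few genes of large change, Ccl5 and the interferons named above. It was the 1 list of 31 whose camera call held with an estimated correlation (limma camera, adjusted p = 2.48e-43, and adjusted p = 0.021 with an estimated correlation). With TMM scaling the adjusted p = 0.216 with an estimated correlation. NF-kappaB targets had a median of 0.42 (adjusted p = 0.030, and adjusted p = 0.761 with an estimated correlation), and 1 of 21 was called, Tnfaip3, which restrains NF-kappaB signalling. It went from 305 ± 51.7 to 1403 ± 942, a log2 fold change of 1.97 ± 0.54 (adjusted p = 0.027). The list's call was lost without Het 3 (adjusted p = 0.060), Het 4 (0.066), KO 1 (0.293) or KO 2 (0.097), and that of Tnfaip3 without any of Het 1 (0.427), Het 2 (0.179), Het 3 (0.128), Het 4 (0.155) or KO 1 (0.407).

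Among stress-response lists, targets of the integrated stress response and ATF4 had positive log2 fold changes in 28 of 28 members, with a median of 0.72 (limma camera, adjusted p = 3.36e-08, and adjusted p = 0.761 with an estimated correlation). Called were 2 members, and 5 adjusted over the list alone. With TMM scaling the list's median lay at 1.09 and 0.70 in KO 1 and KO 2 but at 0.17 and 0.21 in KO 3 and KO 4, below the 0.33 of Het 3. With KO 3 and KO 4 only, the call was lost under the deposited scaling (adjusted p = 0.067) and kept with a mean of at least 200 and TMM factors. Atf3, a stress-induced transcription factor, went from 421 ± 116 to 2636 ± 1269, a log2 fold change of 2.56 ± 0.57 (adjusted p = 0.0012, and 0.057 without Het 2). Trib3, a pseudokinase induced by ATF4, went from 382 ± 121 to 1819 ± 1303, a log2 fold change of 2.03 ± 0.55 (adjusted p = 0.026, and 0.225, 0.304, 0.059 and 0.310 without Het 1, 2, 3 and 4 and 0.419 without KO 1). Psph and Slc7a11, of serine synthesis and cystine uptake, had log2 fold changes of 1.52 ± 0.45 and 1.40 ± 0.45 (adjusted p = 0.064 and 0.136). With TMM scaling, 3 members were called and 10 adjusted over the list alone. Targets of p53 and apoptosis genes had a median of 0.81 (adjusted p = 1.06e-08, and adjusted p = 0.761 with an estimated correlation), with 3 of 22 called and 5 adjusted over the list alone. The 3 were Phlda3 (1.98 ± 0.40), Eda2r (1.67 ± 0.41) and Bbc3 (1.69 ± 0.42), the last of which encodes the pro-apoptotic protein PUMA. Without KO 1 their adjusted p was 0.052, 0.953 and 0.319. The call of Eda2r was also lost without Het 2 or Het 3, with TMM (0.363) or quantile scaling (0.060), without trend or robust settings (0.189) and with edgeR (0.158). That of Bbc3 was lost without Het 3 or Het 4 and without trend or robust settings (0.150). Among members with a mean of at least 200 the list was not called with TMM factors (median 0.18, camera adjusted p = 0.059). Immediate early and heat shock genes, which cell dissociation induces, also had a median of 0.83 (adjusted p = 0.00016, and adjusted p = 0.761 with an estimated correlation), with 17 of 18 positive. None of them was called by limma under the deposited scaling (5 higher and 0 lower at an unadjusted p under 0.05). Of the count tests, edgeR called 0 (9 higher at that unadjusted p) and DESeq2 2 higher (10 at that p).

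Chaperones of the endoplasmic reticulum and targets of XBP1 and ATF6, which fold secreted proteins, fell as a list (median −0.28, limma camera, adjusted p = 0.046), with 18 of 23 negative, and adjusted p = 0.825 with an estimated correlation. The call was lost without Het 2 (adjusted p = 0.066), Het 3 (0.368), KO 3 (0.310) or KO 4 (0.746), and also with no filter on low values and with DESeq2. With TMM scaling the median was −0.49 (adjusted p = 0.00055, and adjusted p = 0.786 with an estimated correlation). With that scaling it was −0.24, 0.26, −0.80 and −1.24 in KO 1 to KO 4, so there the fall lay mainly in KO 3 and KO 4. With a mean of at least 200 and TMM factors the median was −0.52 (camera adjusted p = 1.6e-05, and 0.373 with an estimated correlation). In that setting the list was also called lower with KO 1 and KO 2 only, and on leaving out each library (highest camera adjusted p = 0.0013, without KO 4). Derl3, of the degradation of misfolded proteins, had a log2 fold change of −1.21 ± 0.43 under the deposited scaling (adjusted p = 0.262) and was called with TMM scaling (−1.43 ± 0.29, adjusted p = 0.019). Calr, an abundant chaperone, was at 12722 ± 4037 in Het and 9514 ± 8610 in KO (adjusted p = 0.913).

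Beta-cell identity genes were not called under the deposited scaling. The median over 32 tested members was −0.11 (limma camera, adjusted p = 0.444), and limma, edgeR and DESeq2 called 0 members. At an unadjusted p under 0.05 limma had 0, edgeR 1 higher and 2 lower, and DESeq2 1 higher. Rfx6 and Isl1, transcription factors of endocrine cells, had log2 fold changes of 0.72 ± 0.52 and 0.67 ± 0.53. Npy and Trpm5, a neuropeptide and a taste-pathway channel, had −0.65 ± 0.40 and −0.68 ± 0.54. With genes of a mean of at least 200 and TMM factors, the list fell (median −0.34, camera adjusted p = 0.0048, and adjusted p = 0.425 with an estimated correlation). Of 25 genes of stimulus-secretion coupling and exocytosis, limma under the deposited scaling, edgeR and DESeq2 called 0. At an unadjusted p under 0.05 limma and DESeq2 had 0 of these genes and edgeR 1 lower. Their median log2 fold change was within 0.01 of 0 under the deposited scaling (camera adjusted p = 0.571). They fell with the other setting (median −0.24, adjusted p = 0.0011, and adjusted p = 0.373 with an estimated correlation), and with TMM scaling their median was 0.03 and 0.31 in KO 1 and KO 2 and −0.75 and −0.46 in KO 3 and KO 4. Under the deposited scaling both lists passed without KO 2 (adjusted p = 0.0014 and 0.0088). Chga, a granule protein, was at 121028 ± 32710 in Het and 96888 ± 78332 in KO (adjusted p = 0.948), and Kcnj11, a subunit of the ATP-sensitive potassium channel, at 645 ± 178 and 890 ± 530 (adjusted p = 0.967). In single KO libraries, with TMM scaling, the identity list's median lay at −0.07 and 0.31 in KO 1 and KO 2 and at −0.61 and −0.55 in KO 3 and KO 4. Genes that beta cells keep low or express before maturity had a median of −0.20 over 18 (adjusted p = 0.082), with 0 called (1 higher and 1 lower at an unadjusted p under 0.05; edgeR and DESeq2 0), and Aldh1a3 among them a log2 fold change of −1.05 ± 0.43 (adjusted p = 0.486). That list passed without Het 3 (0.022), KO 1 (0.028) or KO 4 (0.035).

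Cholesterol synthesis genes fell as a list of 20, with a median of −0.45 (limma camera, adjusted p = 0.0076) and −0.67 with TMM scaling (adjusted p = 2.47e-07). With an estimated correlation the adjusted p = 0.761 and 0.511. None was called by limma under the deposited scaling, by edgeR or by DESeq2. At an unadjusted p under 0.05 limma had 1 lower, edgeR 6 lower and DESeq2 0. With TMM scaling 4 were lower adjusted over the list alone. With that scaling the list's median was −0.86, 0.21, −0.71 and −1.28 in KO 1 to KO 4, so KO 2 did not fall. Under the deposited scaling the list's call was lost without Het 3 (camera adjusted p = 0.124), KO 3 (0.073) or KO 4 (0.320). It was also lost with KO 1 and KO 2 only (0.830), with libraries of both sexes only (0.640) and with DESeq2. With a mean of at least 200 and TMM factors the cholesterol list was called lower (median −0.73, camera adjusted p = 3.9e-06, and 0.373 with an estimated correlation). In that setting the call held with KO 1 and KO 2 only and on leaving out each library (highest camera adjusted p = 5.2e-05, without KO 4). Cytosolic ribosomal protein genes rose as a list, with 36 of 36 positive and a median of 0.61 (adjusted p = 0.00012, and adjusted p = 0.761 with an estimated correlation). None of the 36 was called by limma under the deposited scaling, by edgeR or by DESeq2. At an unadjusted p under 0.05 limma had 0, edgeR 6 higher and DESeq2 13 higher. With a mean of at least 200 and TMM factors limma called 2 higher. With KO 3 and KO 4 only the list was not called (camera adjusted p = 0.313). With TMM scaling its median was 0.80, 0.44 and 0.64 in KO 1, 2 and 3 and −0.22 in KO 4, below each Het library. Nuclear-encoded oxidative phosphorylation genes had a median of 0.34 (adjusted p = 0.022, and adjusted p = 0.825 with an estimated correlation), a call lost without Het 1 (0.068), Het 4 (0.134), KO 1 (0.099) or KO 2 (0.383). Mitochondrially encoded messenger RNAs had a median of 0.35 (adjusted p = 0.0083, and adjusted p = 0.761 with an estimated correlation), lost without Het 1 (0.072) or KO 2 (0.383). Glycolysis genes had a median of −0.02 (adjusted p = 0.571, and 0.048 without KO 2). With a mean of at least 200 and TMM factors they were called lower as a list (median −0.25, camera adjusted p = 0.0045, and 0.373 with an estimated correlation). In that setting 14 of 14 were negative, and the call held on leaving out each library (highest camera adjusted p = 0.025, without KO 4). Proliferation genes had a median of −0.16 (adjusted p = 0.522), with Ccne1, cyclin E, called (1.66 ± 0.40, adjusted p = 0.0058, and 0.111 with TMM scaling, with the call also lost without Het 2, Het 4 or KO 1). RNA editing enzymes and partners had a median of 0.20 (adjusted p = 0.635), and −0.02 with TMM scaling.

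**Figure D3:**
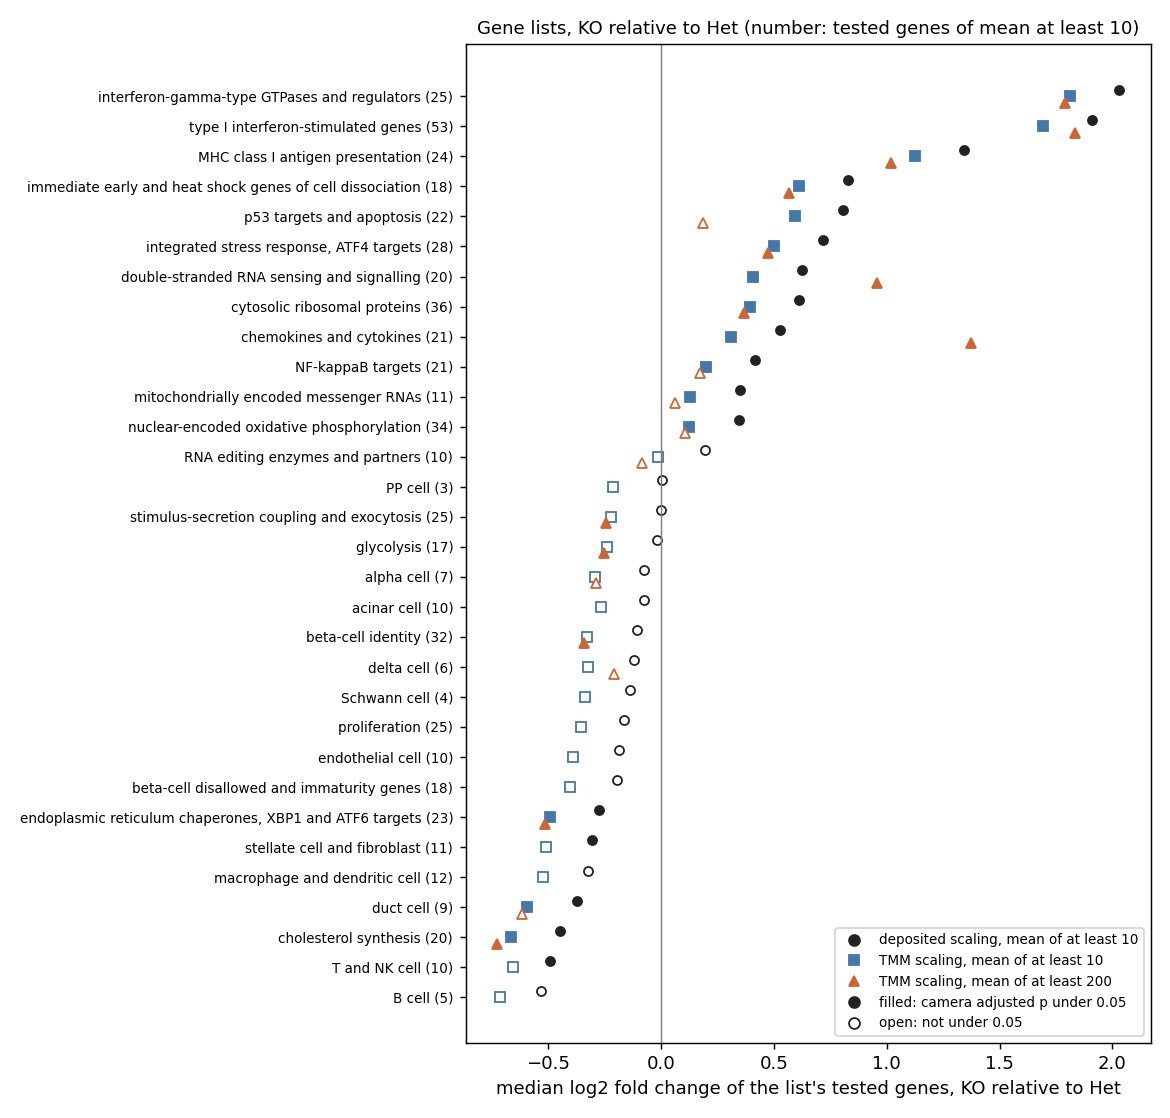
Median log2 fold change (x axis, KO relative to Het) of each list's tested genes (y axis, number tested after the name) under 3 settings. Filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. The 2 interferon lists lie furthest to the right, at 1.91 and 2.03 under the deposited scaling, and most other lists lie within 1 log2 unit of 0.

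Markers of other cell types did not rise as groups over the 4 KO libraries. With KO 3 and KO 4 only, the acinar (limma camera, adjusted p = 0.0044), endothelial (0.047) and stellate cell lists (0.040) were called higher. The macrophage and dendritic cell list had a median of −0.33 over 12 genes (limma camera, adjusted p = 0.571), and its called members moved apart. Cd74, the invariant chain of MHC class II (chromosome 18, 60803848 to 60812652), went from 13.7 ± 1.31 to 253 ± 311, a log2 fold change of 3.41 ± 0.40. C1qa, of complement C1q, made by macrophages (chromosome 4, 136895917 to 136898803), went from 227 ± 43.8 to 86.9 ± 83.1, a log2 fold change of −1.79 ± 0.43 (adjusted p = 0.0051, and 0.066, 0.082 and 0.094 without Het 1, Het 2 and KO 4). Its KO 2 value, 208, lies within the Het range of 164 to 265, and it was not called with DESeq2 (adjusted p = 0.292) or without trend or robust settings (0.127). T and NK cell markers had a median of −0.50 (adjusted p = 0.046, and adjusted p = 0.761 with an estimated correlation), and −0.66 with TMM scaling, where the list was no longer called (adjusted p = 0.169). The call was also lost on leaving out Het 1 (0.103), Het 4 (0.141), KO 1 (0.199) or KO 2 (0.788). Stellate cell and fibroblast markers had −0.31 (adjusted p = 0.012, and adjusted p = 0.761 with an estimated correlation), and −0.51 with TMM scaling, with 11 of 11 negative but no call (0.070). That call was also lost without KO 1 (0.064) or KO 2 (0.821). Duct cell markers had −0.37 (adjusted p = 0.046, and adjusted p = 0.761 with an estimated correlation), lost without Het 2 (0.114), Het 3 (0.193), KO 3 (0.108) or KO 4 (0.389). Krt19, a duct keratin, was called lower (−1.69 ± 0.40, adjusted p = 0.0049), but Het 3 held 201 of it against 27.5 to 52.5 in the other Het libraries, and without Het 3 the adjusted p was 0.565 (0.071 without KO 1). B cell (median −0.53, adjusted p = 0.097), endothelial cell (−0.19, 0.081), Schwann cell (−0.14, 0.771), delta cell (−0.12, 0.781), acinar cell (−0.07, 0.635) and alpha cell lists (−0.07, 0.781, with a mean above 0) were not called, nor was the PP cell list (0.00, 0.571). The B cell list passed without KO 3, and the endothelial list without KO 3 or KO 4. With TMM scaling, the endothelial list lay at −1.31 and −1.65 in KO 1 and KO 2 and at 0.70 and 0.33 in KO 3 and KO 4. The T and NK list lay at −1.25 and −1.86 and at 0.71 and 0.36. These libraries are also those with the lowest and the highest share of receptor gene reads. Lists of erythroid cells and neutrophils had 2 tested members each, with no gene above a mean of 26.9, and were not tested.

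The 5 genes called lower under the deposited scaling were C1qa, Krt19, Crb2 (−1.52 ± 0.42), Gm4815 (−1.71 ± 0.46) and 5830444B04Rik (−1.46 ± 0.40), of which C1qa was also called lower with TMM scaling (−2.01, limma adjusted p = 0.0034). The last 3 were named after their values were seen. No gene met the rule for the largest falls. Among the 8 called lower with TMM scaling, also named after their values were seen, were C1qa, Derl3, Cit (−1.74 ± 0.28), 1110002E22Rik (−1.54 ± 0.27), Rtl1 (−1.23 ± 0.25), Ccdc88c (−1.10 ± 0.23) and Kcnk9 (−1.29 ± 0.28), the last of which encodes a potassium channel.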

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

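Of the tests in this part, those of leukocytes, of sex and of the receptor gene share were chosen only after the result was seen. In 276 groups of 4 libraries, 12 had 1 library that stood apart from the other 3, where chance gives about 13.8. Ifnb1 in KO 1 was at 1250, with the other KO libraries from 148 to 167. Ifna4 in KO 1 was at 1168 (others 146 to 206), Zbp1 at 1915 (341 to 447) and Icam1, an adhesion molecule, at 228 (43.0 to 51.8). In Het 1, Tnfaip3 was at 228 (others 324 to 341) and Xist at 19.2 (4103 to 6425). In Het 4, Chgb was at 26160 (others 41451 to 42492) and Apobec3 at 187 (285 to 286). Acot7 was at 7.77 in KO 2 (14.3 to 15.4), Irx2 at 8.82 in KO 3 (16.7 to 17.0) and Col1a1 at 17.1 in Het 3 (32.4 to 36.3).

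The number of genes called under the deposited scaling does not exclude chance. Of the 35 splits of the 8 libraries into 4 and 4, 3 gave at least the 203 calls of the real split, the real split included, and the others of the 3 gave 206 and 12474. The split with 12474 sets Het 1, Het 4, KO 3 and KO 4 against the rest, the libraries with the highest shares of receptor gene reads, so it points to a structure of the samples that is not genotype. With genes of a mean of at least 200 and TMM factors, 1 of the 35 splits, the real one, gave as many as its 688 calls, and the highest other gave 0. That share is under the 5% set in advance, but it is the smallest that 35 splits can give and the setting was chosen only after the result was seen.

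Expressed genes differed in level between KO libraries under the deposited scaling, and the share of receptor gene reads went with a lower level over the 8 libraries (Spearman rho −1, exact two-sided permutation p = 4.96e-05, the smallest it can give). Both values are read from the same counts, so this association shows a difference in composition and not which genes set the size factors, and whether reads from outside beta-cell transcripts did is left open. If they were genomic DNA, silent X-linked genes should be about 1 copy per cell in Het 1, with reads of males only, for 2 in KO 3 and KO 4, with reads of females only. Their reads relative to autosomal receptor genes were 0.698 times as many (95% interval 0.623 to 0.782), which narrowly meets the bound set in advance (at most 0.7, interval under 1), so genomic DNA is a candidate explanation, though the ratio is above the 0.5 of pure DNA. In a comparison that was not set in advance, libraries of both sexes should lie between 3.61 X-linked reads per 100 autosomal in Het 1 and 5.29 in KO 4, where Het 4 was at 4.67 but Het 2, Het 3, KO 1 and KO 2 at 6.20, 6.35, 7.34 and 13.6, which DNA alone does not give.

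Interferon-stimulated genes were higher in KO. Leukocytes among the sorted cells would bring their own markers, and the 27 tested markers of macrophages, T and NK cells and B cells had a median log2 fold change of −0.40 (quartiles −0.57 and −0.19), with 5 positive. With TMM scaling the T and NK list lay at −1.25, −1.86, 0.71 and 0.36 in KO 1 to KO 4. It lay at 0.39 and 0.45 in Het 1 and Het 4, where the interferon list was at −0.08 and 0.20. The B cell, endothelial and stellate cell lists were positive in the same libraries, those with the highest shares of receptor gene reads. These marker levels may follow reads from outside beta-cell transcripts. Neither they nor the median of the 27 markers can therefore exclude leukocytes. The macrophage list was at 0.38 and 0.37 in KO 3 and KO 4, above each Het library, and was not called with these 2 only (camera adjusted p = 0.522). Among the libraries of both sexes the median log2 fold change of the type I list was 2.48, and 1.81 with TMM scaling. Holding both sexes does not balance them. Ddx3y was at 812 and 1285 in KO 1 and KO 2 and at 198 to 396 in Het 2 to Het 4. With TMM scaling the type I list was at 1.17 and 1.67 in KO 3 and KO 4, of females only. It was at 2.53 and 1.18 in KO 1 and KO 2, and at −0.08 in Het 1, of males only. The rise was thus seen in KO libraries with and without male reads, which argues against sex alone as its cause. The rise goes with the genotype the design names, and a response of the beta cells to loss of Adar remains a hypothesis that was not tested here.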

How the results depend on the processing

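Settings described as KO 1 and 2 only, KO 3 and 4 only, both sexes only, and a mean of at least 200 with TMM were chosen only after the result was seen. Genes higher numbered 198, and 320 with quantile normalization, 127 without trend or robust settings, 404 with a mean of at least 200 and TMM, 9809 with KO 1 and 2 only, 8538 with both sexes only, and, with a mean of at least 200 and TMM, 145 with KO 1 and 2 only and 316 with KO 3 and 4 only. Genes lower numbered 5, and 2 with a mean of at least 50, 8 with TMM, 138 with quantile normalization, 1 without trend or robust settings, 18 with array weights, 8 with edgeR, 3 with DESeq2, 284 with a mean of at least 200 and TMM, 3182 with KO 1 and 2 only, 1587 with KO 3 and 4 only, 2049 with both sexes only, and, with a mean of at least 200 and TMM, 98 with KO 1 and 2 only and 312 with KO 3 and 4 only. Lists called numbered 17, and 1 with an estimated correlation, 0 with fry, and, with a mean of at least 200 and TMM, 0 with an estimated correlation and 6 with fry. The 6 were the lists of type I interferon-stimulated genes, interferon-gamma-type GTPases, double-stranded RNA sensing, MHC class I, chemokines and the integrated stress response. The cause was not tested, except that KO 1 and KO 2 carry higher levels of expressed genes under the deposited scaling. Leaving out 1 library gave 105 to 338 genes higher, 1 to 46 lower, 14 to 16 lists called, and a log2 fold change of Adar of 0.33 to 1.23. With a mean of at least 200 and TMM it gave 121 higher and 22 lower without Het 1, 126 and 22 without Het 2, 182 and 65 without Het 3, 197 and 90 without Het 4, 147 and 47 without KO 1, 646 and 586 without KO 2, 611 and 503 without KO 3, and 285 and 175 without KO 4. The log2 fold change of Adar was 1.63 with KO 1 and 2 only and 1.61 with both sexes only, both past the threshold, and −0.13 with KO 3 and 4 only (adjusted p = 0.869). With a mean of at least 200 and TMM it was 0.59 with KO 1 and 2 only (adjusted p = 0.104) and 0.47 with KO 3 and 4 only (0.212).

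The direction reversed in 16 other values. With a mean of at least 200 and TMM, the adjusted p of mitochondrially encoded messenger RNAs was 0.916, and 0.966 with an estimated correlation, 0.943 with fry and 0.555 with KO 1 and 2 only. With all libraries the median of that list was still 0.06 in this setting, so there only the direction of the test changed. With KO 1 and 2 only, that of endoplasmic reticulum chaperones was 0.433, and the log2 fold changes of Slc2a1 and Tm4sf4 were 0.77 and 0.70. With both sexes only, the adjusted p of endoplasmic reticulum chaperones was 0.530 and the log2 fold change of Slc2a1 0.81. With KO 3 and 4 only, the adjusted p was 0.432 for NF-kappaB targets, 0.237 for oxidative phosphorylation, 0.0044 for acinar, 0.116 for T and NK, 0.047 for endothelial and 0.040 for stellate cell markers, and 0.844 for mitochondrially encoded messenger RNAs. Of 3821 values of named genes and lists under the alternatives, 3392 kept their direction or were not called either way, 232 passed the threshold newly and 181 no longer did, and 163 changed sign without a call. DESeq2 gave no adjusted p for 18 named genes, among them Ifna4, Ifnb1, Ifnl2, Ifnl3 and Zbp1. The labels do not say whether the replicate numbers pair the libraries, and the values showed no clear pairing. Deviations of same-numbered libraries correlated at −0.28, 0.27, −0.55 and 0.63 (0.22, −0.05, 0.13 and 0.28 with a mean of at least 200 and TMM), and 2 of 8 libraries correlated best with their own number. The replicate block gave 182 genes higher and 5 lower, and Tnfaip3, Trib3, the endoplasmic reticulum chaperones and the T and NK cell markers lost their calls with it (adjusted p = 0.066, 0.067, 0.061 and 0.052). KO 3 held the fewest reads, 5.37 M, and the effect of depth on the calls of low genes was not tested.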

Other observations

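The test in this part was chosen only after the result was seen. Host genes of small nucleolar RNAs, whose introns carry them, were among the genes that rose. Snhg12 went from 65.4 ± 13.6 normalized counts in Het to 457 ± 301 in KO (SD, n = 4 each), a log2 fold change of 2.39 ± 0.25 with TMM scaling (limma adjusted p = 7.01e-05). Snhg1 went from 96.6 ± 23.3 to 442 ± 280 (1.81 ± 0.25, adjusted p = 0.00089) and Gas5 from 308 ± 94.5 to 1181 ± 758 (1.56 ± 0.27, adjusted p = 0.0065). Under the deposited scaling Gas5 did not pass the threshold (1.78 ± 0.53, adjusted p = 0.078).

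A hypothesis is that host transcripts rise as a class in KO. Among the 16 other tested members, the median log2 fold change with TMM scaling was 0.80, 12 were positive, and 4 were called higher and 0 lower. These were Zfas1 (2.19 ± 0.28), Snhg15 (1.99 ± 0.27), Epb41l4aos (2.52 ± 0.41) and Snhg5 (1.48 ± 0.25). Camera gave p = 4.06e-11 for the 16, and p = 0.0074 with an estimated correlation, which is consistent with the hypothesis. Snhg18, Snhg20 and Snhg7os had log2 fold changes of −0.43, −0.26 and −0.41, so the class did not move as 1 unit. Many host transcripts begin with the pyrimidine tract that ribosomal protein messenger RNAs carry. Ribosomal protein genes were called higher as a list. That call did not hold for camera with an estimated correlation (adjusted p = 0.761, and 0.537 with TMM scaling). Among genes of a mean of at least 10, limma called 0 of the 36, and their TMM median was −0.22 in KO 4. The small nucleolar RNAs overlap their host genes, so what was counted cannot be resolved here.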
